A study of Mus musculus with 6 samples.

How the data were processed

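RNA of S2 and S3 proximal tubule segments of C57Bl/6 mice was sequenced 24 h after a dose of 3 mg/kg of aristolochic acid I or of DMSO, with 3 libraries per group. Per the labels' protocols, tubules were dissected by hand, RNA was isolated with a PicoPure kit and libraries were made with the TruSeq Stranded mRNA kit. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19, kallisto was named without a version or role, and the genome build was mm10. How transcripts were joined to genes, the annotation, the strand setting of the counting and any rounding are not given in the sources used here.

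The authors deposited 1 table of 32544 genes and 6 libraries with log10 values. The base and the added 1 were read from the values themselves: the values are log10(CPM + 1), since after undoing the logarithm each column adds up to the total that CPM implies and low values are whole multiples of a single step. Before the data were examined the table had been assumed to hold log2 CPM; the values were therefore turned back to CPM and logged again as log2(CPM + 1). Whole reads could be recovered for 100% of the values within 0.1 read. Library depths ran from 13304877 to 31136251 reads, so that 1 read stood for 0.0752 to 0.0321 CPM. Of the gene symbols, 27 had been turned into dates and 2 occurred more than once.

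Genes with at least 1 CPM in at least 3 libraries were tested (14311 genes), with the moderated t-test of limma 3.58.1 with a variance trend in R 4.3.3. P-values were two-sided and adjusted over all tested genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error of the log2 fold change of AA over DMSO. Values of a gene are means and SD of CPM over 3 libraries. On simulated data with 200 changed genes, this test recovered 43.0% of 2-fold and 80.0% of 4-fold changes, with 5.4% false calls and 0 calls of the wrong sign. In the simulation 14277 genes were tested, whereas 4426 of 14311 genes were called in the data. The changed share was far smaller in the simulation, so these recovery rates need not hold for the data.

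Before the data were examined, 29 lists of gene groups and 13 lists of cell markers were fixed that had at least 5 tested members; 6 of them were primary: p53 targets, S phase, G2 and mitosis, tubular injury, transporters, and fatty acid oxidation. The lists were written from general knowledge. Each was tested with camera, with a preset correlation of 0.01 between genes, adjusted over the 42 lists. As alternatives, camera with an estimated correlation and the rotation test fry were run. The members that passed were counted at the adjusted p over all genes, and again with the adjustment over the list alone.

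Genes to be named were fixed by a rule before the data were examined. It takes the 10 largest increases and 10 largest decreases among called genes without overlap between groups and with a mean log2 value of at least 3, leaving out pseudogenes and predicted genes. It adds up to 4 members per list with the smallest adjusted p, or the 2 highest expressed members where none passes. It also always takes Cdkn1a, Mdm2, Havcr1, Lcn2, Krt20, Slc22a6, Slc22a8, Slc34a1, Lrp2, Nqo1, Cyp1a1, Mki67, Ppara, Atf3 and Trp53. Genes outside the rule are said to have been named after their values were seen.

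Gene coordinates and lengths came from GENCODE M21, matched by symbol for 13895 tested genes (97.1%). The trend with gene length was the Spearman correlation between log2 fold change and genomic length, and partial rank correlations used exonic length and GC content. The 6 libraries were permuted exactly.

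Alternatives fixed before the data were examined were equalised library medians, quantile normalization, TMM factors (own implementation), no filter and a filter of 4 CPM, a pseudocount of 5, no variance trend, a robust variance, array weights, a replicate block, a 2-fold bound and leaving out each library. A planned pseudocount of 1 coincided with the fit used. Added after the data were examined were voom on recovered reads, a pseudocount of 0.1, reads thinned to the smallest library, a term for the library sets (DMSO replicates 1 and 2 against DMSO replicate 3 and AA), removal of pseudogenes and predicted genes, and the length trend under the further settings. The library-set term leaves the AA effect resting on DMSO replicate 3. Genes of the Y chromosome were read in all 6 libraries, for example Ddx3y at 48.8 to 81.1 CPM.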

Results

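The libraries measured polyadenylated RNA in kidney proximal tubules of C57Bl/6 mice, collected 24 h after an injection of aristolochic acid I or of its solvent, dimethyl sulfoxide (DMSO). Aristolochic acid I is a plant nephrotoxin that is reduced in cells and then forms bulky adducts on DNA. The stated dose was 3 mg/kg. Tubules of the S2 and S3 segments, the later parts of the proximal tubule, were dissected by hand, and 5 to 10 of them were pooled per kidney. The comparison asks how transcription in these segments responds to the toxin. Each group had 3 libraries, called AA and DMSO replicates 1 to 3 here. The labels do not say whether the 3 libraries of a group came from separate animals, so every p-value measures only the spread between these libraries.

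Reads counted per library were 23896026, 31136251 and 15958557 in DMSO replicates 1, 2 and 3, and 13304877, 17815915 and 13926322 in AA replicates 1, 2 and 3. Of 32544 genes in the table, 14311 reached 1 CPM (counts scaled to the library total) in at least 3 libraries and were tested. The correlation of log2 values was 0.970 to 0.980 within groups and 0.918 to 0.95 between groups. The first principal component held 64.0% of the variance and separated AA from DMSO. Within the DMSO group, replicates 1 and 2 stood apart from replicate 3 and from all AA libraries for 44 genes, by more than 2 on the log2 scale. Of those 44 genes, 43 were pseudogenes or predicted genes. Values of AA against DMSO replicate 3 alone, and tests with a term for these sets of libraries, therefore stand beside the results. Such a test rests on 1 control library. The mitochondrial share of reads was 8.65%, 4.01% and 10.1% in the DMSO libraries and 8.72%, 5.60% and 4.82% in the AA libraries.

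AA tubules differed from DMSO tubules in 4426 of the 14311 tested genes in limma's moderated test with Benjamini-Hochberg adjustment at 0.05. Of these, 3187 were higher and 1239 were lower in AA. Counts of list members below stand against these shares of the 14311 tested genes, and a list near them shows no particular response. A change of at least 2-fold was found for 1689 of them, 1278 higher and 411 lower. The AA and DMSO values did not overlap in 46.4% of tested genes, against 10% by chance for 3 against 3. The median log2 fold change of all tested genes was 0.21, and the scaling of the libraries moved the split of the calls. The share of higher calls was 72.0% as deposited, 39.9% when library medians were equalised (1606 higher, 2422 lower), 46.7% after quantile normalization (1822 and 2077) and 48.8% with TMM factors (1952 and 2051). Medians of some gene groups are therefore also given relative to 0.21, and are then called relative. All other list medians are not shifted, so they include this change of all genes. With the term for the library sets, 1481 genes passed, of which 994 higher and 401 lower genes were shared with the 4426. Leaving out AA replicate 2 left 2645 genes, and applying no filter on low values left 1375 genes.

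The rule for naming the largest increases and decreases required no overlap between AA and DMSO values. Of the individual genes named in the text, 135 passed the test. All 135 had AA values beyond every DMSO value, which by itself fixes their sign against DMSO replicate 3. The call of 72 of them held with no filter on low values, that of 96 with the library-set term, and that of 111 whichever library was left out. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values.

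**Figure D1:**
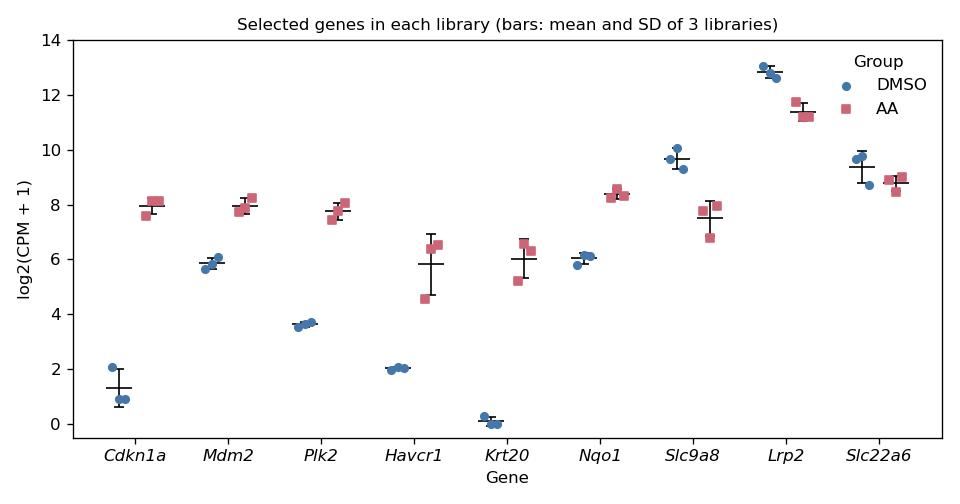
Levels of 9 genes in each of the 6 libraries, as log2(CPM + 1), with DMSO libraries as blue circles and AA libraries as red squares; black bars give the mean and SD of 3 libraries. The 3 AA values lie above all DMSO values for Cdkn1a, Mdm2, Plk2, Havcr1, Krt20 and Nqo1 and below them for Slc9a8 and Lrp2, whereas those of Slc22a6 overlap.

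Most of the p53 target genes rose in AA tubules. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 1.67 ± 1.38 CPM in DMSO to 249 ± 49.5 CPM in AA (mean ± SD, n = 3 each), a log2 fold change of 6.64 (SE 0.30, limma adjusted p = 8.87e-07). Mdm2, whose product targets p53 for degradation, went from 57.1 ± 8.37 to 249 ± 49.8 CPM, with a log2 fold change of 2.10 (SE 0.17, adjusted p = 1.82e-05). Phlda3 rose from 4.26 ± 1.46 to 109 ± 11.4 CPM, Btg2 from 6.16 ± 1.19 to 135 ± 31.8 CPM and Plk2 from 11.4 ± 0.841 to 217 ± 44.5 CPM. Trp53 itself, which is not on the list, went from 32.4 ± 2.87 to 78.7 ± 10.8 CPM, a log2 fold change of 1.25 (SE 0.15, adjusted p = 0.000237). Cdkn1a lies on chromosome 17 from 29090976 to 29100727 on the plus strand, and Mdm2 on chromosome 10 from 117688875 to 117710758 on the minus strand (mm10).

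Of 47 tested p53 target genes, 38 were higher, 1 was lower and 8 did not pass; adjusted over the list alone, 40 were higher and 1 was lower. The lower gene was Gria3, a glutamate receptor subunit, with a log2 fold change of -0.79, named after its values were seen. The list's median log2 fold change was 1.70, or 1.49 relative to all genes, and camera, limma's set test, gave an adjusted p of 3.26e-18. The adjusted p was 0.363 with an estimated correlation between the genes and 0.00158 in fry, a rotation test. Against DMSO replicate 3 alone the median was 1.67, and with the library-set term 35 members were higher and 1 was lower.

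Injury and dedifferentiation genes of the proximal tubule were higher in AA. Havcr1, which encodes the tubular injury marker KIM-1, rose from 3.08 ± 0.158 to 65.1 ± 37.3 CPM (n = 3), a log2 fold change of 3.79 (SE 0.42, adjusted p = 0.00014). Krt20, a keratin with 0 reads in DMSO replicates 2 and 3, went from 0.0698 ± 0.121 to 69.1 ± 29.1 CPM, and Fosl1 from 0.233 ± 0.136 to 29.2 ± 14.3 CPM. Atf3 had a log2 fold change of 3.81 (SE 0.39), Tnfrsf12a one of 3.25 (SE 0.22) and S100a10 one of 1.83 (SE 0.15). Lcn2, the gene of the injury marker NGAL, reached 4.08 ± 2.87 CPM from 0.271 ± 0.0545 CPM, a log2 fold change of 1.85 (SE 0.37, adjusted p = 0.00426). Havcr1 lies on chromosome 11 from 46735080 to 46779578 on the plus strand.

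Of 46 tested injury genes, 35 were higher, 0 were lower and 11 did not pass; adjusted over the list alone, 38 were higher and 0 were lower. The median log2 fold change was 1.31 and the camera adjusted p was 5.53e-11, or adjusted p = 0.363 with an estimated correlation and 0.00474 in fry. In the library-set test 22 members were higher and 0 were lower, and the median against DMSO replicate 3 was 1.28. Thin limb markers were also higher for 4 of 6 members. Of 9 markers of collecting duct principal cells, 4 were higher and 1 was lower (camera adjusted p = 0.182). A link of these markers to the injury genes was not tested. Lcn2 was highest in AA replicate 2 (7.30 CPM, against 3.16 and 1.80 CPM in AA replicates 1 and 3), the library that also had the most Aqp2 (66.5 CPM) and Cldn19 (28.8 CPM).

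More transporters of the proximal tubule were lower than higher in AA. Slc9a8, a sodium-hydrogen exchanger, fell from 838 ± 222 to 190 ± 72.3 CPM (n = 3), a log2 fold change of -2.19 (SE 0.28, adjusted p = 0.000382). Slc13a2, a citrate transporter, fell from 81.9 ± 17.7 to 24.4 ± 2.04 CPM, a log2 fold change of -1.69 (SE 0.17, adjusted p = 8.45e-05). Slc22a28 had a log2 fold change of -1.39 (adjusted p = 0.000831) and Slc5a10, a sodium-coupled sugar transporter, one of -0.90 (SE 0.14). The transporters that rose were Slc7a12 (log2 fold change 1.37) and Slc34a3 (0.92), and, named after their values were seen, Slc13a1 (1.09), Slc5a2 (0.71) and Slc20a2 (0.47); with library medians equalised, 2 transporters passed as higher. Slc22a28, Slc22a30 and Slc7a12 belong to families of similar copies, between which reads can be shared, and their levels are uncertain to that extent.

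Of 57 tested transporters, 5 were higher, 21 were lower and 31 did not pass; adjusted over the list alone, 8 were higher and 26 were lower. The median log2 fold change was -0.41, or -0.61 relative to all genes, and the camera adjusted p was 1.86e-08, or adjusted p = 0.408 with an estimated correlation and 0.0716 in fry. Against DMSO replicate 3 alone the median was -0.11, and with the library-set term 4 members were higher and 5 lower, with a camera adjusted p of 0.00116. Of 11 tested markers of the S3 segment, 1 was higher, 6 were lower and 4 did not pass, with a median of -0.90. The camera adjusted p was 8.58e-06, or 0.363 with an estimated correlation. Adjusted over the list alone, 1 was higher and 8 were lower. Most S3 markers, among them Slc5a10, Slc22a30, Slc7a12 and Slc7a13, are also on the transporter list. The S3 result is therefore not independent of that of the transporters. Acy3 is not on the transporter list. Acy3, an aminoacylase of the S3 segment, fell from 2075 ± 705 to 437 ± 70.3 CPM, a log2 fold change of -2.20 (SE 0.23). Of 9 S1 segment markers, 2 were higher, 3 lower and 4 did not pass; adjusted over the list alone, 3 were higher and 3 lower. Their median was 0.45 and their mean 0.10, while the direction in camera was downward (adjusted p = 0.622). Of the S1 markers, 0 were higher and 3 lower with library medians equalised, and with the library-set term 0 and 1.

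The organic anion transporters that carry aristolochic acid into tubule cells did not pass. Slc22a6, which encodes OAT1, had 698 ± 248 CPM in DMSO and 445 ± 80.7 CPM in AA (n = 3), a log2 fold change of -0.59 (SE 0.26, adjusted p = 0.103). It was 0.08 against DMSO replicate 3 alone, and without that replicate it was -0.93 with an adjusted p of 0.00376. Slc22a8, which encodes OAT3, had a log2 fold change of 0.26 (SE 0.28, adjusted p = 0.507), and 1.04 against DMSO replicate 3 with an adjusted p of 0.0134 in the library-set test. The phosphate transporter Slc34a1 had a log2 fold change of -0.62 (SE 0.29, adjusted p = 0.122), 0.02 against DMSO replicate 3, and -0.93 without that replicate (adjusted p = 0.0134). The endocytic receptors megalin and cubilin fell: Lrp2 went from 7282 ± 1121 to 2704 ± 637 CPM, a log2 fold change of -1.44 (SE 0.25, adjusted p = 0.00199), and Cubn from 1681 ± 207 to 776 ± 37.4 CPM, a log2 fold change of -1.11 (SE 0.16, adjusted p = 0.000746). With no filter on low values the adjusted p of Lrp2 was 0.387.

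Fatty acid oxidation and peroxisome genes were divided. Acsm1 (log2 fold change -1.39, SE 0.17), Amacr (-0.98, SE 0.14) and Acox2 (-0.93, SE 0.14), enzymes of fatty acid activation and of peroxisomal oxidation, were lower in AA (n = 3 each). Pdk4, a kinase that restrains the oxidation of glucose, rose from 17.5 ± 3.81 to 129 ± 22.1 CPM, a log2 fold change of 2.82 (SE 0.18, adjusted p = 6.05e-06). The thioesterase gene Acot2, named after its values were seen, was the other higher member, with a log2 fold change of 0.64. Ppara, the nuclear receptor that drives many of these genes, fell from 87.2 ± 8.92 to 59.2 ± 5.99 CPM, a log2 fold change of -0.55 (SE 0.14, adjusted p = 0.0141). This call was lost without AA replicate 2 (adjusted p = 0.064), with the library-set term (0.175) and with no filter (0.0715).

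Of 54 tested members, 2 were higher, 16 were lower and 36 did not pass, and the counts adjusted over the list alone were 2 and 16. The median log2 fold change was 0.00, the mean was -0.11, and the median relative to all genes was -0.21. The camera adjusted p was 0.00103, or adjusted p = 0.584 with an estimated correlation and 0.373 in fry. The call was also lost after quantile normalization (adjusted p = 0.256) and with the library-set term (0.311), where 4 members were higher and 4 lower.

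Neither list of cell cycle genes passed as a group. Of 46 tested genes of DNA replication and S phase, 9 were higher, 4 were lower and 33 did not pass, with the same counts adjusted over the list alone. The camera adjusted p was 0.75, with a downward direction. The median (0.10) and mean (0.18) were above 0, but relative to all genes the median was -0.10. Pcna, the polymerase clamp, rose from 24.9 ± 2.94 to 72.6 ± 5.83 CPM, a log2 fold change of 1.51 (SE 0.15, n = 3), and Mcm7 and Cdt1 had log2 fold changes of 1.34 and 1.45. The lower members, named after their values were seen, were Pole, Chaf1a, Prim2 and Mcm10, with log2 fold changes of -1.03, -0.95, -0.84 and -0.79. These 4 calls were lost with the library-set term (adjusted p = 0.109, 0.126, 0.139 and 0.255), where 3 members of the list were higher and 0 lower. With library medians equalised, 6 members were higher and 7 lower.

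Of 35 tested genes of G2 and mitosis, 6 were higher, 2 were lower and 27 did not pass; adjusted over the list alone, 3 were higher and 2 were lower. The camera adjusted p was 0.732, with a downward direction, while the median was 0.25, or 0.04 relative to all genes. Aspm, a spindle gene, was higher (log2 fold change 1.59, SE 0.29), whereas the kinesin genes Cenpe (-1.59, SE 0.30) and Kif20b (-1.08, SE 0.21) were lower. Mki67, the proliferation marker, stood at 2.03 ± 0.533 CPM in DMSO and 2.76 ± 1.54 CPM in AA, with a log2 fold change of 0.25 (SE 0.32, adjusted p = 0.573), which was -0.01 with library medians equalised. With library medians equalised, 1 member of the list was higher and 2 were lower.

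None of the 3 lists of DNA repair and damage signalling passed in camera as a group. Of 37 nucleotide excision repair genes, 6 were higher, 2 lower and 29 did not pass, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.664, 0.0245 in fry and 0.908 with an estimated correlation). Ercc5, which encodes the repair endonuclease XPG and is also on the p53 list, rose from 26.2 ± 4.33 to 97.6 ± 19.1 CPM (n = 3), a log2 fold change of 1.85 (SE 0.18). The lower members were Gtf2h2 (-0.62) and, named after its values were seen, Pole. Of 32 genes of the Fanconi anaemia and homologous recombination list, 2 were higher, 0 were lower and 30 did not pass, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.174, with a downward direction). Its higher members were Mus81 (0.94) and Faap24 (0.73). This list passed after quantile normalization (0.0324; 1 higher, 7 lower) and with the library-set term (0.0218; 0 higher, 1 lower), and had an adjusted p of 0.908 with an estimated correlation. Of 30 damage checkpoint genes, 6 were higher, 1 was lower and 23 did not pass, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.856). Cdc25a had a log2 fold change of 0.85 (SE 0.20), H2afx one of 1.10 (SE 0.21), and the damage kinase gene Atm was the lower member at -0.78 (SE 0.19). With the library-set term the adjusted p was 0.117 for Atm, 0.0565 for H2afx, 0.0719 for Mus81, 0.115 for Faap24 and 0.138 for Gtf2h2. With library medians equalised, higher and lower members numbered 3 and 3 in the excision repair list, 1 and 3 in the Fanconi list and 3 and 5 in the checkpoint list.

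Antioxidant genes of the NRF2 pathway rose. Srxn1 went from 35.6 ± 1.83 to 257 ± 28.3 CPM (n = 3), a log2 fold change of 2.81 (SE 0.13, adjusted p = 8.87e-07). Nqo1, a reductase that also reduces aristolochic acid, went from 65.1 ± 9 to 333 ± 43.4 CPM, a log2 fold change of 2.34 (SE 0.15, adjusted p = 6.02e-06). Hmox1 and Txnrd1 had log2 fold changes of 2.25 (SE 0.16) and 1.61 (SE 0.13). Of 36 tested members, 27 were higher, 1 was lower and 8 did not pass; adjusted over the list alone, 29 were higher and 1 was lower. The lower gene, named after its values were seen, was the cystine transporter gene Slc7a11, with a log2 fold change of -0.79. The median was 0.96 and the camera adjusted p was 8.46e-10, or adjusted p = 0.363 with an estimated correlation. In the library-set test 18 members were higher and 0 were lower.

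Of 8 tested aryl hydrocarbon receptor genes, 4 were higher, 0 were lower and 4 did not pass, or 5 and 0 adjusted over the list alone. Nfe2l2, which encodes NRF2 itself, had a log2 fold change of 1.68 (SE 0.13), and Cyp1b1 one of 0.96 (SE 0.21). Ahr, at 0.78, and Ugt1a6a, at 1.20, were the others; Ugt1a6a shares exons with other genes of its cluster. The camera adjusted p was 0.0325, or adjusted p = 0.583 with an estimated correlation. The list's call was lost with the library-set term (adjusted p = 0.0588), without AA replicate 2 (0.0565), without DMSO replicate 2 (0.0683) and without the variance trend (0.0536); with the library-set term the adjusted p was 0.156 for Cyp1b1, 0.0806 for Ahr and 0.0752 for Ugt1a6a. Cyp1a1, the classical target of this receptor, stayed below the filter, with at most 9 reads in an AA library and 3 in a DMSO library, so that a change was not detectable at this depth.

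Of 17 tested genes of aristolochic acid uptake and metabolism, 4 were higher, 2 were lower and 11 did not pass, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.531, 0.0282 in fry and 0.908 with an estimated correlation). The higher members were Nqo1, Xdh (log2 fold change 1.09, SE 0.21), Sult1b1 (1.15) and, named after its values were seen, Ptgs2 (1.00). The lower members were the sulfotransferase gene Sult1c2 (-0.70) and, also named after its values were seen, the oxidoreductase gene Por (-0.85). With the library-set term, 3 members were higher and 0 were lower.

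Inflammatory and immediate early genes were higher in AA. Cxcl1, a neutrophil chemokine, rose from 1.40 ± 0.667 to 41.2 ± 22.8 CPM (n = 3), a log2 fold change of 4.02 (SE 0.38, adjusted p = 5.39e-05), and complement C3 from 6.22 ± 0.605 to 98.3 ± 44.1 CPM. Nfkb2 and Icam1 had log2 fold changes of 2.54 (SE 0.17) and 2.32 (SE 0.21). Of 28 tested NF-kB and cytokine genes, 22 were higher, 0 were lower and 6 did not pass, or 26 and 0 adjusted over the list alone (median 1.41, camera adjusted p = 3.31e-10; adjusted p = 0.363 with an estimated correlation). Klf6, Junb and Jun, transcription factors of the early response, had log2 fold changes of 3.04 (SE 0.17), 2.89 (SE 0.17) and 2.73 (SE 0.18). Of 18 immediate early genes, 16 were higher, 0 were lower and 2 did not pass, with the same counts adjusted over the list alone (median 2.34, camera adjusted p = 5.53e-11; adjusted p = 0.363 with an estimated correlation). Under the library-set term, 15 NF-kB and 14 immediate early genes were higher and 0 were lower.

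Interferon response genes rose as well: of 40 tested, 24 were higher, 0 were lower and 16 did not pass, or 26 and 0 adjusted over the list alone. Tap1, a peptide transporter of antigen presentation, went from 5.56 ± 1.63 to 28.4 ± 5.68 CPM, a log2 fold change of 2.18 (SE 0.24, n = 3), and Ifit3 and Ifit2 had log2 fold changes of 1.90 (SE 0.23) and 1.60 (SE 0.22). The median was 0.91 and the camera adjusted p was 2.87e-06, or adjusted p = 0.408 with an estimated correlation. Of 28 cell death genes, 13 were higher, 0 were lower and 15 did not pass, or 17 and 0 adjusted over the list alone (camera adjusted p = 0.00186; adjusted p = 0.408 with an estimated correlation). Those that rose act on both sides of cell death: Mcl1, which protects cells, had a log2 fold change of 1.26 (SE 0.14), and Mlkl, which executes necroptosis, one of 1.72 (SE 0.28). With the library-set term, 12 interferon and 4 cell death genes were higher and 0 were lower. Some macrophage and myeloid markers were higher too. Of 16 tested, 6 were higher, 0 were lower and 10 did not pass, and the counts adjusted over the list alone were 6 and 0. With the library-set term or after quantile normalization 1 was higher and 0 lower, and with library medians equalised 2 were higher and 1 lower. Cd68, a lysosomal glycoprotein of macrophages, went from 0.933 ± 0.485 to 28.4 ± 9.30 CPM, a log2 fold change of 3.91 (SE 0.30). C1qb went from 3.36 ± 0.308 to 7.53 ± 1.23 CPM, a log2 fold change of 0.96 (SE 0.23). The rise of Cd68 was far larger than that of C1qb and than the list's median of 0.60. Which cells the Cd68 reads came from was not tested. The camera adjusted p of this list was 0.0416, or adjusted p = 0.408 with an estimated correlation, and the call was lost without AA replicate 1 (0.13), DMSO replicate 2 (0.0565) or DMSO replicate 3 (0.0983). The adjusted p of C1qb was 0.0526 without AA replicate 2, 0.0685 with the library-set term and 0.072 after quantile normalization.

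**Figure D2:**
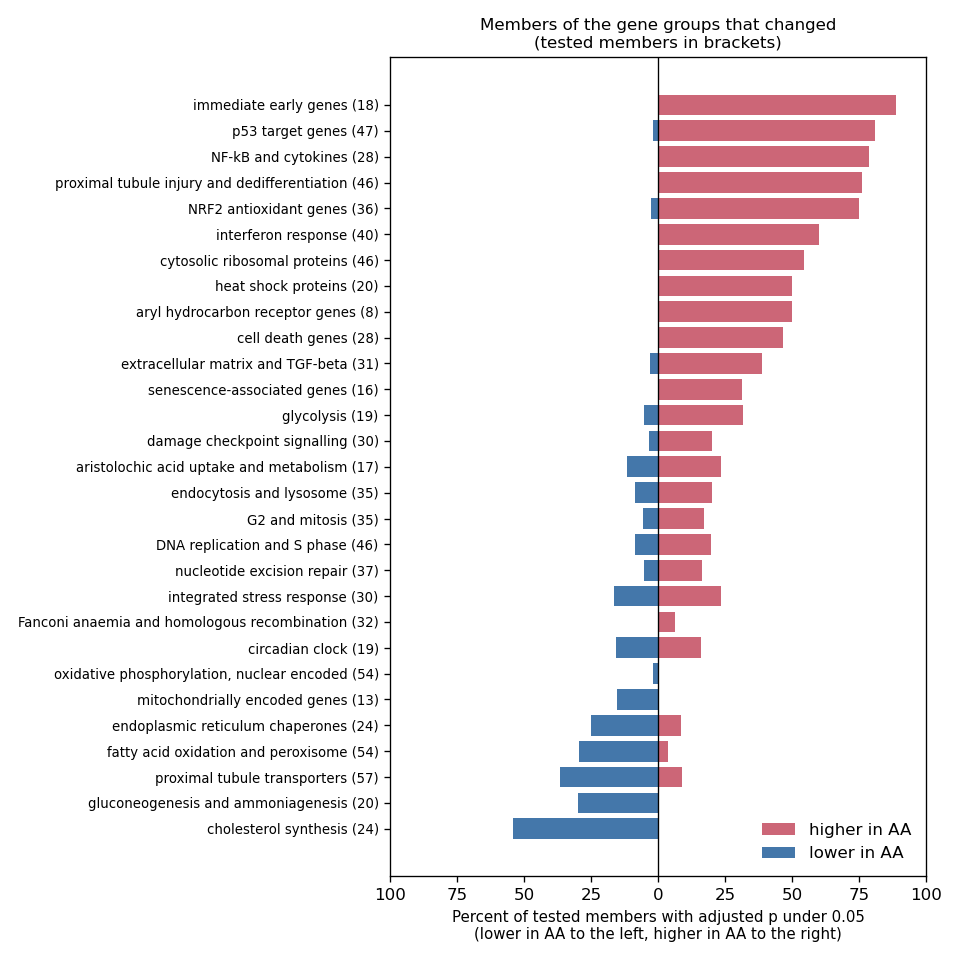
Percent of the tested members of each of 29 gene groups that were higher in AA (red, to the right) or lower in AA (blue, to the left) at an adjusted p of 0.05, with the number of tested members in brackets. Immediate early genes (16 of 18 higher) and p53 targets (38 of 47 higher) stand at the top, and cholesterol synthesis genes (13 of 24 lower) at the bottom. The balance of the groups in between shifts with the scaling of the libraries. Of all 14311 tested genes, 3187 were higher and 1239 were lower.

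Among well expressed genes, the largest increases and decreases were chosen by a fixed rule. Besides Cdkn1a, Krt20, Phlda3, Btg2, Plk2 and Cxcl1, the 10 largest increases were those of Enc1 (log2 fold change 4.67), Gdf15 (4.22), Sfn (3.87) and Arg2 (3.79). Gdf15 encodes a stress-induced cytokine and was also on the p53 list. The 10 largest decreases included the potassium channel genes Kcnma1 (-2.88, SE 0.30) and Kcng1 (-2.56, SE 0.32), the xylosyltransferase gene Xylt1 (-2.79, SE 0.20), Fras1 (-2.64, SE 0.23), Aspg (-2.62, SE 0.32), Nat8f6 (-2.81, SE 0.32) and the water channel gene Aqp4 (-2.83, SE 0.39), with n = 3 per group. Xylt1 went from 56.2 ± 12.5 to 7.16 ± 0.942 CPM, and Fras1, a basement membrane gene, from 153 ± 48.0 to 23.4 ± 6.04 CPM. Xylt1 spans 292.6 kb of chromosome 7 from 117380979 to 117673580, and Kcnma1 spans 725.1 kb of chromosome 14 from 23289431 to 24014491. The calls of the other 3 were lost with the library-set term. Grip2 had 107 and 152 CPM in DMSO replicates 1 and 2, 3.07 CPM in DMSO replicate 3 and 2.25 to 2.80 CPM in AA, so that its log2 fold change of -3.52 (SE 1.02) became -0.20 against DMSO replicate 3. Lars2 went from 1610 ± 2020 to 78.7 ± 19.98 CPM with a log2 fold change of -3.40 (SE 0.76), and -3.17 against DMSO replicate 3 (adjusted p = 0.0648 in the library-set test, with 1 control library left). It ran from -2.28 without DMSO replicate 1 to -4.41 without DMSO replicate 2, and the Lars2 call was lost with a robust variance (adjusted p = 0.113). Gfra1 had one of -2.50 (SE 0.54), and -1.32 against DMSO replicate 3 (adjusted p = 0.144).

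Expression change fell with the length of the gene. Across 13895 tested genes with an annotated length, the Spearman correlation between log2 fold change and genomic length was -0.28; genes are not independent replicates. Genes that were lower in AA had a median length of 73.4 kb and those that were higher 15.0 kb, against 23.2 kb for all tested genes. Among 1421 protein-coding genes under 5 kb, 31.2% were higher and 3.31% were lower, with a median log2 fold change of 0.35. Among 342 genes over 320 kb, 10.2% were higher and 40.4% were lower, with a median of -0.47. When library medians were equalised, 16.6% of the short class were higher and 8.02% lower, and 4.97% and 52.3% of the long class. Library by library, the correlation between deviation from the DMSO mean, the reference shared by all, and length was -0.28, -0.23 and -0.30 in AA replicates 1 to 3 and 0.04, -0.06 and 0.03 in DMSO replicates 1 to 3. An exact permutation test of the 6 libraries used another statistic, the correlation of expression level with length in each library. The mean of this correlation in AA minus that in DMSO was -0.08. The test gave a two-sided p of 0.1, the smallest it can give with 3 against 3. Against DMSO replicate 3 alone the correlation between log2 fold change and length was -0.28. With no filter on low values it was 0.06, because genes near 0 reads were then added.

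**Figure D3:**
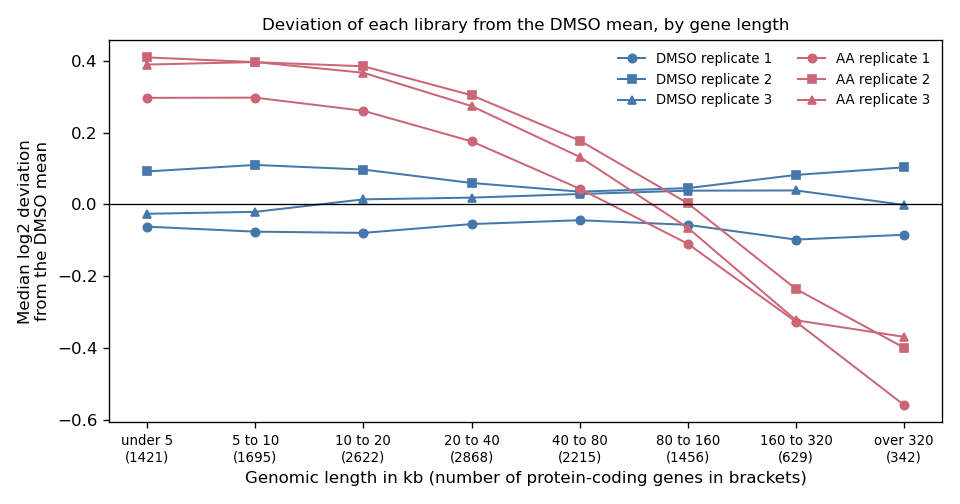
Median log2 deviation of each library from the DMSO mean (vertical axis) in 8 classes of genomic length in kb (horizontal axis), with the number of protein-coding genes in brackets; red lines are AA and blue lines DMSO libraries. The AA medians go from between 0.30 and 0.41 under 5 kb to between -0.56 and -0.37 over 320 kb, and the DMSO medians stay between -0.10 and 0.11.

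Markers of other cells that dissected tubules can carry were tested in the same way. Thin limb markers were higher for 4 of 6 members, with 0 lower and 2 not passing, or 5 and 0 adjusted over the list alone. The camera adjusted p was 0.0135, or 0.408 with an estimated correlation. Cryab went from 142 ± 24.5 to 465 ± 61.1 CPM (n = 3). It is also on the list of heat shock genes, of which 10 of 20 were higher, so its rise is not specific to thin limb cells. Fibroblast and mural cell markers were higher for 6 of 13, with 0 lower and 7 not passing, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.583 with an estimated correlation, and 0.0627 without AA replicate 1). Of these, 3 were higher after quantile normalization and 1 with the library-set term. Gsn had a log2 fold change of 0.90 (SE 0.18). Endothelial markers were higher for 3 of 12, with 0 lower and 9 not passing, or 8 and 0 adjusted over the list alone. Over all tested genes 3187 of 14311 were higher, a share close to 3 of 12. The camera adjusted p of the endothelial list was 0.0452, or 0.69 with an estimated correlation. Tek, a receptor, and Cdh5, an adhesion molecule of endothelial cells, had log2 fold changes of 0.84 (SE 0.16) and 0.85 (SE 0.19). The endothelial call in camera was lost without AA replicate 1 (0.0864), AA replicate 2 (0.0822) or DMSO replicate 3 (0.283). It was also lost with the stricter filter (0.0543), no variance trend (0.0623), voom (0.0523), thinned reads (0.0531) and without pseudogenes and predicted genes (0.0511). Fry gave an adjusted p of 0.0716. The endothelial median was 0.55, and it was larger, at 0.73, against DMSO replicate 3 alone.

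Of 9 principal cell markers of the collecting duct, 4 were higher, 1 was lower and 4 did not pass, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.182). The list passed with library medians equalised (0.0445) and with the library-set term (0.0227), and had an adjusted p of 0.746 with an estimated correlation. The water channel genes Aqp2 and Aqp4 on this list moved apart. Aqp2 went from 8.29 ± 1.07 to 43.4 ± 20.9 CPM (n = 3), a log2 fold change of 2.16 (SE 0.29). Aqp4 went from 93.7 ± 56.7 to 11.7 ± 5.05 CPM. In DMSO its level was thus far above that of Aqp2, and which cells its reads came from was not tested. Fxyd4 and Gata3 had log2 fold changes of 1.58 (SE 0.22) and 1.43 (SE 0.25), and Hsd11b2, named after its values were seen, one of 1.14. Of 9 thick ascending limb markers, 3 were higher, 1 was lower and 5 did not pass, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.732); Cldn19 had a log2 fold change of 1.65 (SE 0.35). Of 8 podocyte, 8 intercalated cell and 6 lymphocyte markers, 1 each was higher, 0 were lower, and the camera adjusted p was 0.708, 0.622 and 0.732; 1 each was higher adjusted over the list alone. The higher members were Synpo, Foxi1 and Cd79a, and their adjusted p with the library-set term was 0.0664, 0.0952 and 0.0858. None of 6 distal convoluted tubule or 5 erythroid markers passed in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.871 each). The neutrophil list had too few tested members for a set test, and its receptor gene Cxcr2 had a log2 fold change of -0.29 (SE 0.25, adjusted p = 0.4), which ran from -0.45 to -0.07 when 1 library was left out.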

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

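The library-set term, voom, the pseudocount of 0.1, thinned reads and the removal of pseudogenes were chosen after the result was seen; the other settings were fixed before. Each of the 4426 calls kept its sign under every change of scaling and every left-out library, and 4422 kept it with the library-set term. No variance trend, a robust variance, the replicate block, the changed filters and the removal of pseudogenes leave the log2 fold change as it is. The sign could not change there, and the counts below include these settings. The called named genes had no overlap between groups. Their sign was therefore also fixed with the library-set term and whichever library was left out. Of 2825 values of the called named genes, 2612 kept their call, 213 lost it and 0 reversed. Of 788 values of the secondary and marker lists, 720 kept their side of the threshold, 42 lost a call and 26 gained 1. These labels follow the camera test: the median itself changed sign in 33 of 377 values of the 19 lists without a call. The robust variance has no camera test. Voom on recovered reads called 4363 genes. Where no cause is named below, the cause was not tested.

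Equalised library medians (median-centred) gave 1606 higher and 2422 lower genes, by construction of the shift, with Slc22a8 at -0.000755 and Mki67 at -0.00566; Slc22a6 then passed (adjusted p = 0.0433 in limma). Quantile normalization gave 1822 and 2077 genes, a relative median of -0.0724 for G2 and mitosis and of -0.0438 for fatty acid oxidation (adjusted p = 0.256), and -0.0782 for Mki67. TMM gave 1952 and 2051 genes.

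With no filter on low values, 1375 genes passed (1009 higher, 366 lower), with 32544 genes adjusted for. Because the median of all genes was then 0, the relative medians were 0.10 for S phase and 0.000783 for fatty acid oxidation. The length trend was 0.0572 from the added genes. The stricter filter left 2 marker lists passing, a relative median of -0.0768 for G2 and mitosis and a length trend of -0.31. A pseudocount of 5 gave -0.0382 for G2 and mitosis. Voom left 3 marker lists and thinned reads left 3 marker lists.

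With the library-set term 1481 genes passed (1058 higher, 423 lower), with fewer control libraries behind the estimate. Relative medians were -0.0644 for G2 and mitosis and -0.12 for fatty acid oxidation (adjusted p = 0.311 in camera), and Slc22a6 and Slc34a1 had log2 fold changes of 0.0825 and 0.0183. The 2-fold bound left 1689 genes (1278 higher, 411 lower). With exonic length the length trend was -0.16.

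Camera with an estimated correlation left 0 gene lists and 0 marker lists; the relative medians 1.49 (p53), 1.10 (injury), -0.61 (transporters) and -0.21 (fatty acid oxidation) did not depend on it, and the adjusted p was 0.363, 0.363, 0.408 and 0.584. In fry, transporters (-0.61) had an adjusted p of 0.0716 and fatty acid oxidation (-0.21) of 0.373.

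Leaving out 1 library, which leaves fewer samples, gave 2645 (without AA replicate 2) to 3980 genes (without DMSO replicate 3), 1842 to 2839 higher and 803 to 1141 lower. Marker lists passing ran from 2 (without AA replicate 1) to 5 (without AA replicate 3). The relative median of G2 and mitosis ran from -0.0611 to 0.0749, Slc22a8 from -0.13 to 0.52 and Mki67 from -0.0584 to 0.48.

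With the replicate number as a replicate block, 3813 genes passed (2768 higher, 1045 lower). Libraries of the same number shared only the number: their deviations correlated at -0.109, -0.156 and -0.0151, and 0 libraries correlated best with their own number. Depth limits genes such as Cyp1a1, with at most 9 reads.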

Other observations

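Cholesterol synthesis genes fell in AA tubules: of 24 tested, 0 were higher, 13 were lower and 11 did not pass, with the same counts adjusted over the list alone (median -0.61, camera adjusted p = 2.73e-09; adjusted p = 0.363 with an estimated correlation). Cyp51, a sterol demethylase, went from 529 ± 106 to 166 ± 39.97 CPM (n = 3), a log2 fold change of -1.67 (SE 0.20), and Mvd and Hmgcs1 had -1.14 and -0.86; with the library-set term 5 members were lower. Gluconeogenesis and ammoniagenesis genes were lower for 6 of 20, with 0 higher and 14 not passing, and 0 and 6 adjusted over the list alone (camera adjusted p = 0.00157; adjusted p = 0.583 with an estimated correlation, and 0.256 after quantile normalization). With the library-set term 0 were higher and 0 lower, and the median against DMSO replicate 3 was -0.07, with -0.21 in the fit used; fry gave an adjusted p of 0.173. Pck1 went from 3582 ± 1688 to 1200 ± 165 CPM, a log2 fold change of -1.49, with an adjusted p of 0.0846 in the library-set test. Of 19 glycolysis genes, 6 were higher, 1 was lower and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.354, 0.0471 with the library-set term and 0.908 with an estimated correlation), and 3 and 1 with the library-set term or equalised medians; Pkm and Hk1 had log2 fold changes of 1.16 and 1.22 and Pfkp one of -0.64. Pkm and Hk1 were highest in AA replicate 2 (231 and 110 CPM, against 121 and 47.0 CPM in AA replicate 1 and 138 and 48.0 CPM in AA replicate 3), the library that also had the most Aqp2 and Cldn19, markers of later segments. Of 46 ribosomal protein genes, 25 were higher, 0 lower and 21 did not pass, or 27 and 0 adjusted over the list alone. Their median was 0.42, or 0.21 relative to all genes. The camera adjusted p was 0.00082, or 0.613 with an estimated correlation. Rpl15 and Rpl7 had log2 fold changes of 0.79 and 0.77. Of the 46, 7 were higher with library medians equalised and 7 with the library-set term; pseudogene copies make their levels uncertain. Mitochondrially encoded genes were lower for 2 of 13 (mt-Nd6 -1.15, mt-Nd4l -1.20), with 0 higher and 11 not passing. The counts adjusted over the list alone were the same. The camera adjusted p was 0.00292, or 0.668 with an estimated correlation and 0.394 after quantile normalization, and fry gave 0.407. With equalised medians 4 were lower. The list's median was -0.50, and -0.96 against DMSO replicate 3 alone. The mt-Nd4l call was lost in limma with a robust variance (adjusted p = 0.0775) and without AA replicate 2 (0.0629) or AA replicate 3 (0.0548). Of 54 nuclear genes of oxidative phosphorylation, 0 were higher, 1 was lower (Ndufb10, -0.54) and 53 did not pass, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.0592). With library medians equalised, 7 were lower and the list passed (camera adjusted p = 0.00289), and leaving out 1 library gave 0.00126 (DMSO replicate 3) to 0.632 (DMSO replicate 1). It was 0.908 with an estimated correlation. Ndufb10 had a log2 fold change of -0.27 against DMSO replicate 3 alone. Its call in limma was lost without AA replicate 1 (adjusted p = 0.0932), AA replicate 3 (0.122), DMSO replicate 1 (0.0913) or DMSO replicate 2 (0.104).

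Of 24 endoplasmic reticulum chaperones, 2 were higher, 6 lower and 16 did not pass, or 2 and 8 adjusted over the list alone (median -0.26, camera adjusted p = 0.000166; adjusted p = 0.363 with an estimated correlation). Herpud1 had a log2 fold change of -0.88, Atf6 one of -0.72 and Dnajb9 one of 1.25; 1 was higher and 0 lower with the library-set term, and 1 and 14 with equalised medians, 2 and 12 with TMM and 3 and 9 after quantile normalization. Heat shock genes rose for 10 of 20, with 0 lower and 10 not passing, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.00334; adjusted p = 0.541 with an estimated correlation). Hspa1a and Hspa1b had log2 fold changes of 2.70 and 2.62; these near-identical copies share reads. With library medians equalised, 7 heat shock genes were higher and 2 lower. Of 30 integrated stress genes, 7 were higher, 5 lower and 18 did not pass, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.856); 5 and 6 with equalised medians and 6 and 3 with the library-set term. Slc3a2 (2.09) and Ddit3 (1.66) rose, and Phgdh, Aldh1l2, Slc7a11, Shmt2 and Vldlr, named after their values were seen, had -1.38, -1.32, -0.79, -0.74 and -0.56. Of 19 clock genes, 3 were higher and 3 lower, also adjusted over the list alone, and 13 did not pass (camera adjusted p = 0.354): Nfil3 (1.69), Usp2 (-1.32), Hlf (-0.75), Tef (-0.69) and, named after their values were seen, Cry1 (1.05) and Arntl (1.04). The calls of Cry1 and Arntl were lost with equalised medians (adjusted p = 0.0744 and 0.0848), quantile normalization, TMM and the library-set term (0.126 and 0.338), and Arntl had 0.69 without AA replicate 2 (0.143). Of the clock genes, 1 was higher and 4 lower with equalised medians, and 2 and 2 with the library-set term. Of 31 extracellular matrix and TGF-beta genes, 12 were higher, 1 was lower (Lama3, -2.29) and 18 did not pass. Adjusted over the list alone, 14 were higher and 1 lower, and with equalised medians 6 and 3. The camera adjusted p was 0.0954, or 0.678 with an estimated correlation. Leaving out 1 library gave 0.0230 (DMSO replicate 2) to 0.268 (AA replicate 1). The median was 0.47, and 0.41 against DMSO replicate 3 alone. Fibroblast and mural cell markers, which share collagen genes with this list, were also higher for 6 of 13. Of 16 senescence genes, 5 were higher, 0 lower and 11 did not pass, also adjusted over the list alone (camera adjusted p = 0.117, 0.0367 with the library-set term and 0.408 with an estimated correlation), and 4 and 1 with equalised medians and 3 and 0 with the library-set term; Cdkn1a, Cxcl1 and Trp53 were among the higher members. Of 35 endocytosis and lysosome genes, 7 were higher, 3 lower (Lrp2, Cubn and, named after its values were seen, Atp6v0a4, -0.50) and 25 did not pass, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.856); with library medians equalised, 1 was higher and 5 were lower, and with the library-set term 2 and 2.

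The tests on pseudogene share and on S3 markers were chosen after the result was seen; the others below were fixed before. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, namely itself with 4426, and the highest other gave 0; this share cannot go below 0.1.

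Among the genes that separate DMSO replicates 1 and 2 from the other 4 libraries, 97.7% were pseudogenes or predicted genes, against 5.80% of the 69 genes that separate AA from DMSO. This is in line with reads of similar copies having been assigned differently in 2 sets of libraries. Of 2756 genes called in AA replicates 1 and 2 against DMSO replicates 1 and 2, 92.1% had the same sign in AA replicate 3 against DMSO replicate 3, so the set alone does not account for the changes. The median ratio of the 2 fold changes was 0.80.

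The fall of expression change with gene length could reflect transcription stopped at aristolochic acid adducts, which a long gene is more likely to carry. This hypothesis was fixed before the data were examined, and adducts were not measured. The correlation was -0.28; the values by library share the DMSO mean as reference and are no separate test. Given exonic length and GC content it was -0.24. This is against a loss of long transcripts only as far as annotated exonic length and GC content capture it. No measure of RNA quality was used, so RNA quality is left open. Against DMSO replicate 3 alone the correlation was -0.28, against the library set as the cause. Length does not separate this from other responses in which long genes fall.

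The fall of S3 markers and transporters, lists that share members, may be regulation within cells or fewer S3 cells in the AA tubules. For the transporters it may also lie partly in the control libraries, since their median against DMSO replicate 3 alone was -0.11. The median of the S3 markers against that replicate was -0.75. Of the 11 S3 markers, 3 had a 95% interval wholly above the list median of -0.90: Slc7a12 (1.37), and, named after their values were seen, Cyp7b1 (-0.22) and Slc7a13 (-0.24). When 1 library was left out, Cyp7b1 ran from -0.38 to -0.13 and Slc7a13 from -0.43 to -0.09. This test was set after the values were seen, and its median comes from the same 11 genes, so a loss of S3 cells is left open. The transporters' median of -0.41 stood at percentile 0 among 10000 random lists matched on length and expression, whose 2.5th percentile was -0.08, so gene length alone does not account for it.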
